A study of Mus musculus with 4 samples.

How the data were processed

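The deposited files were 1 filtered matrix per library of whole-number UMI counts, and the values were counts per the file headers and their content. The headers name Cell Ranger 7.0.1. The submitters' processing notes name STAR and the mm10 build without further versions, and the library kit was the 10x 3' kit, version 3.1, read as paired ends of 150 bases. Whether intronic reads were counted was not given in the sources used here. Gene positions came from the GENCODE vM21 annotation of GRCm38, which is the mm10 assembly, and 99.6% of the 32285 gene identifiers were found in it (32158). The groups, the gene lists, the class markers, the rules for calls and for named genes and most alternative settings were fixed before the data were examined.

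Nuclei were kept when at least 300 genes were detected and at most 10% of counts were mitochondrial, which 74, 98, 23 and 74 nuclei failed in untreated, high-fat, MTZ-after and MTZ-simultaneous. Doublets were scored in each library with Scrublet as built into scanpy. Its automatic threshold marked 12.1% of nuclei in MTZ-after (3400 removed) and 15.3% in MTZ-simultaneous (2949 removed). The threshold marked 0.0% in untreated, for which the rule fixed in advance removed the highest 8% of scores. In high-fat it marked 99.9%; the same removal was used there by a ceiling of 50% that was decided after this value was seen. The numbers removed were 1562 (6.97%) in untreated and 2763 (7.25%) in high-fat, under 8% because the scores took few values and the 247 and 538 nuclei tied at the threshold were kept. In an alternative setting the highest 8% of scores were removed in every library, with ties kept. This took out 6.97, 7.25, 7.73 and 6.92% of scored nuclei in untreated, high-fat, MTZ-after and MTZ-simultaneous. In the main setting, kept nuclei numbered 20780, 35253, 24693 and 16312.

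Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes chosen over libraries gave 30 principal components, without integration of the libraries. Leiden clustering at resolution 1 on a graph of 20 neighbours gave the clusters. Each cluster was named from marker lists of 26 classes when at least 3 markers were detected and enriched at least 2-fold. Clusters with markers of a pair of unrelated classes stayed unnamed. Comparisons within a class used classes with at least 200 nuclei in every library. Surrounding tissue meant adipocyte, brown adipocyte, skeletal muscle, cardiomyocyte, epithelial, thymocyte, thyroid, adrenal and neuron classes, and the share without it had all other kept nuclei, unnamed ones included, as its base.

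Counts were summed per library and class and scaled to the common total of CPM by the sum of all genes. A gene was called higher or lower when the CPM ratio was at least 2 and the library with the higher level held at least 50 counts. A ratio against 0 counts was taken against a floor of 3 counts in that library and is given as "at least". It leaves out counting error in the other library and is not the end of an exact interval. Intervals cover counting error only: exact Poisson for CPM, exact Clopper-Pearson for shares and exact conditional intervals for ratios. For each of 22 gene lists the median log2 ratio (pseudocount of 1 CPM) of members with at least 10 counts over both libraries was set beside 10000 random lists of the same size, drawn for each member from the 50 genes on either side in mean expression; counting ranges came from 1000 Poisson draws. A median is described as within the range of random lists when it lay in the central 95% of them. These values describe the libraries and test no treatment. Most contractile genes were also markers of the smooth-muscle class, as were Mrc1, F13a1 and Cd163 of the resident list for the macrophage class. Nuclei low in such genes could fall outside the class in any comparison, so these medians do not measure their loss freely.

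Named genes were chosen by rule. In each of the 3 comparisons and each of the smooth-muscle, fibroblast, endothelial and macrophage classes these were the 3 genes highest and the 3 lowest by the interval bound nearest to 1, among called genes. The CPM in the class also had to reach 25% of the highest CPM of any class with at least 50 nuclei in the same library, so that free RNA of another class would choose fewer of them. For this rule each unnamed cluster counted as a class of its own. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out. Within a list, the members given as examples were those with the largest bounds, together with Spp1, Mmp12 and others from the fixed lists that were picked after their values were seen. A single list member is not reported here. The comparison of the MTZ libraries with each other used the same rules.

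For shares of nuclei with a UMI, every nucleus was also thinned at random to 500 UMIs, and 0 nuclei fell below that. For the return analysis the high-fat nuclei were split at random into equal parts: genes were chosen from the first part against untreated and measured as the MTZ library against the second part.

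Known changes were planted in simulated counts of the same depths to check the calls. In smooth-muscle-like nuclei, high-fat over untreated (6621 genes), 96.0% of 50 genes changed 2.5-fold were recovered, 100.0% of those changed 4.0-fold and 0.0% of those changed 1.5-fold, with 39 unchanged genes called. For MTZ-after over high-fat (8155 genes) 98.0% at 2.5-fold were recovered and 71 unchanged genes called; for MTZ-simultaneous over high-fat (10614 genes) the values were 92.0% and 235. In macrophage-like nuclei, high-fat over untreated (12346 genes), they were 98.0% and 6. The intervals held the planted value for 95.4% of genes in the first of these. The counts were drawn from the Poisson law that the intervals assume, so this coverage says nothing about variation between nuclei or animals. Planted genes were expected to hold at least 50 counts in the smaller library, so the recovery covers well-counted genes alone.

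The alternatives were stricter filters (500 genes, 5% mitochondrial) and looser ones (200 genes, 20%), doublet calls kept in, Leiden resolution 2, centring of each library, TMM factors, equal weight for each nucleus, thinning, a minimum of 20 counts or none, a pseudocount of 10 CPM, a minimum of 50 counts for list members and exchange or omission of the random split. Added after the data were seen were the removal of the highest 8% of doublet scores in every library, a second clustering seed, all kept nuclei as the base of shares, each macrophage-like cluster alone, the endothelial-like and fibroblast-like shares and list medians under every one of these settings that applies to them, and smooth-muscle-like shares without clusters of which under 50% had that name in the main clustering.

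The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used for TMM factors alone. With 1 library per group no p-value was computed. Raw reads, empty droplets and the animals behind each library were not analysed here, so free RNA could not be estimated from empty droplets.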

Results

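Nuclei from aortic tissue of mice that carry a CA1 (mouse gene Car1) knock-in on an ApoE-deficient background were sequenced as 3' single-nucleus RNA libraries with unique molecular identifiers (UMIs). Carbonic anhydrase 1 is a cytosolic enzyme that interconverts carbon dioxide and bicarbonate, and loss of ApoE makes mice prone to atherosclerosis. There were 4 groups with 1 library each. The groups were mice without treatment (untreated), mice given high-fat food (high-fat), and mice given high-fat food plus MTZ, named methoxazolamide in the labels and described there as an inhibitor of CA1. MTZ was given either once atherosclerosis had developed (MTZ-after) or at the same time as the diet (MTZ-simultaneous). The deposited matrices held 22413, 38114, 28116 and 19335 nuclei in that order. Total UMIs were 69201159 in untreated, 50358151 in high-fat, 31517272 in MTZ-after and 37962370 in MTZ-simultaneous. The median nucleus held 2026, 969, 827 and 1420 UMIs. Without replicate libraries, no difference could be set against the variation between animals, and every interval is a 95% counting interval.

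After filtering, 97038 nuclei formed 32 clusters, and marker genes placed most of them in 13 classes. The classes are called by what they resembled, so "macrophage-like" means a cluster whose leading markers were those of macrophages. Nuclei that stayed without a name made up 19.0% of the kept nuclei in untreated, 42.5% in high-fat, 22.4% in MTZ-after and 5.93% in MTZ-simultaneous. The largest unnamed cluster was led by St18, Ms4a7, Atp6v0d2 and Msr1, the last a scavenger receptor for modified lipoproteins. It held 24.1% of the high-fat nuclei, against 0.765% in untreated, 3.63% in MTZ-after and 1.30% in MTZ-simultaneous. The next was led by Ddah1, Edn1 and Fbln5 and held 17.7% of the high-fat nuclei, against 1.09%, 6.52% and 2.07%. All shares of classes below leave these nuclei out unless stated.

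The libraries differed in the tissue they contained. Brown-adipocyte-like nuclei made up 32.5% of named nuclei in untreated, 3.35% in high-fat, 16.1% in MTZ-after and 8.60% in MTZ-simultaneous. Nuclei like those of the adrenal cortex made up 20.3% of MTZ-after (3896 nuclei), with 1, 1 and 3 nuclei in untreated, high-fat and MTZ-simultaneous. Mesothelial-like nuclei made up 7.55%, 0.276%, 3.01% and 15.3%. Transcripts of such tissue were counted in other classes, and free RNA was not separated from remaining doublets as their source: Ucp1, the brown-fat uncoupling protein, reached 254.2 CPM (UMI counts scaled to a common total) in untreated smooth-muscle-like nuclei and 259.7 CPM in untreated B-cell-like nuclei.

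**Figure D1:**
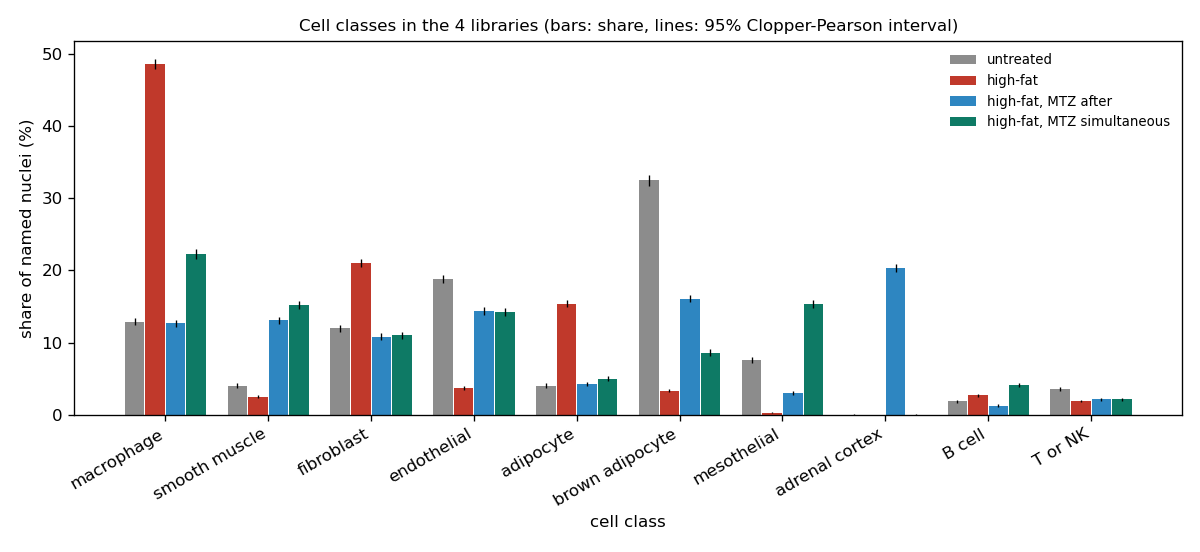
Percentage of named nuclei in each class (bars, starting at 0) for the 4 libraries, with exact 95% intervals. Macrophage-like nuclei made up 12.9% in untreated, 48.6% in high-fat, 12.6% in MTZ-after and 22.3% in MTZ-simultaneous.

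Car1 was counted in every library and in every class compared. The gene (ENSMUSG00000027556) lies on chromosome 3 from 14766216 to 14808368 in the mm10 build, and its level over all kept nuclei was 128.0 CPM (8259 counts, interval 125.2 to 130.8) in untreated. The level was 86.2 CPM (83.5 to 88.9) in high-fat, 64.1 CPM (61.1 to 67.1) in MTZ-after and 151.8 CPM (147.6 to 156.0) in MTZ-simultaneous. Whether the inserted copy is the mouse or the human sequence was not given in the sources used here, so these counts do not separate it from the endogenous gene. Endothelial-like nuclei held the highest level among the large classes in each library, with 239.9, 130.3, 90.4 and 200.2 CPM. Macrophage-like nuclei held 109.2, 88.9, 62.5 and 154.1 CPM, and smooth-muscle-like nuclei 115.8, 96.4, 69.0 and 127.9 CPM. T- or NK-like nuclei, which are not known to express it, held 120.5, 92.3, 66.1 and 146.9 CPM, so the level in macrophage-like and smooth-muscle-like nuclei was not above background by more than counting error.

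The share of endothelial-like nuclei with a Car1 UMI was 38.5% in untreated (median 1981 UMIs), 26.7% in high-fat (2071), 9.06% in MTZ-after (775) and 35.7% in MTZ-simultaneous (1926). Among T- or NK-like nuclei the shares were 18.0% (1433 UMIs), 9.04% (908), 5.37% (767) and 18.5% (1113). With every nucleus thinned to 500 UMIs, the endothelial-like shares were 11.4%, 6.97%, 3.89% and 9.59%, against 5.03%, 3.36%, 3.42% and 6.17% in T- or NK-like nuclei. Apoe (ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188, mm10), whose protein clears lipoproteins, was counted at 9.54, 8.75, 10.8 and 10.8 CPM. The deleted part of Apoe was not given in the sources used here, and 3' tags can lie outside it, so these counts do not check the knock-out.

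**Figure D2:**
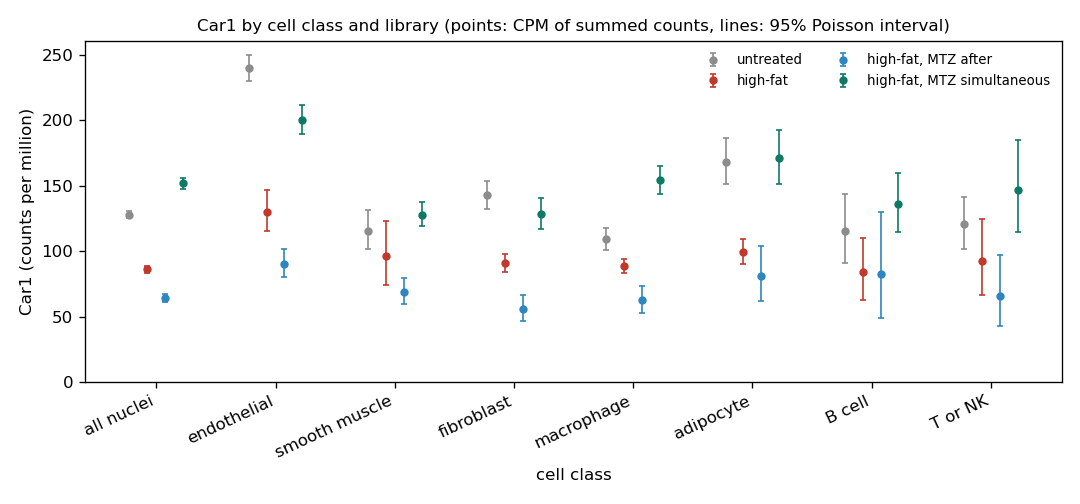
Car1 level (CPM, axis from 0) by class in the 4 libraries, with exact Poisson 95% intervals. Endothelial-like nuclei held 239.9 CPM in untreated and 90.4 CPM in MTZ-after.

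High-fat food given to ApoE-deficient mice fills the arterial intima with lipid-laden macrophages, and smooth muscle cells leave the contractile state for matrix-producing or macrophage-like states. The high-fat library was set against the untreated one to see what the diet does in aorta that carries the CA1 knock-in. It held more macrophage-like nuclei, which had fewer resident-type transcripts and a different mix of clusters. Its smooth-muscle-like nuclei held more transcripts of modulation, matrix and interferon response, but the modulation and matrix lists were also higher in T- or NK-like, B-cell-like and macrophage-like nuclei, so free RNA or doublets were not separated from a change in these nuclei.

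Macrophage-like nuclei made up 48.6% of named nuclei in high-fat (interval 47.9 to 49.3) and 12.9% in untreated (12.4 to 13.4), a ratio of 3.78 (3.61 to 3.96). The ratio was 2.12 without the surrounding-tissue classes and 1.78 when each library was centred before clustering. Smooth-muscle-like nuclei made up 2.49% (505 nuclei) and 4.04% (680 nuclei), a ratio of 0.616 (0.548 to 0.693). This direction turned with stricter filters (1.34) and with centring (1.23). It also turned with the highest doublet scores removed by the same rule in every library (1.18). The share without surrounding tissue gave 0.346. Endothelial-like nuclei made up 3.75% against 18.8%, a ratio of 0.199. This direction turned as well, to 1.46 with stricter filters, 1.07 with looser ones, 1.33 with doublet calls kept in and 1.23 with centring. In those 4 clusterings a cluster with Ddah1 among its leading genes, as in the unnamed cluster that held 17.7% of the high-fat nuclei, was named endothelial-like. Fibroblast-like nuclei made up 21.0% against 12.0%, a ratio of 1.75, which turned to 0.982 without surrounding tissue and to 0.931 with another clustering seed.

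In smooth-muscle-like nuclei, 151 genes were at least 2-fold higher and 346 at least 2-fold lower in high-fat, of 6531 with at least 50 counts in either library. With TMM factors the split was 88 and 501, as those factors shifted the median of all genes by -0.16 on the log2 scale. It was 209 and 165 with another clustering seed, 132 and 136 with stricter filters and 2646 and 1094 with no minimum count. Of the 497 calls, 165 were shared with the other seed, 122 with the stricter filters and 99 with a finer clustering. Of these nuclei, cluster 7 held 67.9% in untreated and 90.1% in high-fat, and cluster 20 the rest. A finer clustering (Leiden resolution 2) named part of them pericyte-like, in a cluster led by Hpse2 and Col19a1: 14.3% of the smooth-muscle-like nuclei of untreated, 39.4% of high-fat, 38.8% of MTZ-after and 14.9% of MTZ-simultaneous. The contractile genes had a median log2 ratio of -0.27, with 14 of 18 lower; Itga8, an integrin of contractile cells, was at a ratio of 0.575 (0.52 to 0.63), Myocd, the coactivator that drives the contractile programme, at 0.66 and the myosin heavy chain Myh11 at 0.806. Most contractile genes, Itga8, Myocd and Myh11 among them, were also markers that named the class, so nuclei low in them could fall outside it. The modulation genes had a median of 1.03, with 16 of 19 higher, including the matricellular gene Thbs1 at 3.19, against 3.53 in endothelial-like nuclei. Foam-cell and lipid-handling genes had a median of 1.18, with 16 of 20 higher. Many of these are macrophage genes, and Spp1 (osteopontin), at 7.00 (6.33 to 7.74), was also at 5.60 in T- or NK-like nuclei. Interferon-response genes had a median of 1.23, with 12 of 13 higher, among them the viral RNA sensor Ddx58 (2.43). Collagen and elastic-fibre genes had a median of 0.47, with Fn1 (fibronectin) at 2.45, against 2.23 in endothelial-like nuclei, and Fbln5 at 2.06. The same lists were higher in T- or NK-like nuclei, with medians of 0.73 for modulation, 1.12 for foam-cell and 0.72 for collagen genes. In macrophage-like nuclei modulation genes were at 1.24 and collagen genes at 1.55. The contractile list was higher there, at 1.29, and at 0.69 in T- or NK-like nuclei, against -0.27 in smooth-muscle-like ones. The collagen gene Col1a1 was at 6.16 in T- or NK-like and at 10.5 in B-cell-like nuclei, which do not make it. Calcification genes had a median of 0.45, whose counting range included 0, with the bone morphogen Bmp4 at 2.74 and the calcification inhibitor Mgp at 2.09. The inflammatory genes had a median of 0.67 and the ER-stress genes 0.65, with the ER chaperone Hspa5 at 1.99 and the unfolded-protein transcription factor Xbp1 at 2.33. TGF-beta response genes had a median of 0.35, which turned to -0.095 with nuclei thinned to equal depth. The endothelial activation and EndMT genes had a median of 0.46, with endothelin 1 (Edn1) at 2.13. In macrophage-like nuclei that list was at 0.88, calcification genes at 0.71 and TGF-beta response genes at 0.55. Inflammatory genes were at 0.34 there and ER-stress genes at 0.30, so free RNA or doublets were not separated from a change in smooth muscle.

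Metabolic lists had lower medians in these nuclei, but the untreated ones included nuclei that other clusterings placed elsewhere. Brown-fat genes had a median of -2.05 with 12 of 12 lower, lipogenesis and lipolysis genes -1.07, and nuclear-encoded oxidative phosphorylation genes -0.68. Another clustering seed named 23.5% of the untreated smooth-muscle-like nuclei brown-adipocyte-like (1.39% of the high-fat ones). Removal of the highest 8% of doublet scores in every library gave 23.8% (1.98%) and stricter filters 19.7% (1.02%). A finer clustering left 29.0% (7.13%) unnamed. With these the brown-fat median was -0.92, -0.79, -0.90 and -1.03, and the lipogenesis median -0.38, -0.31, -0.34 and -0.53. In T- or NK-like nuclei the medians were -2.74 for brown-fat, -1.26 for lipogenesis and -0.74 for nuclear-encoded oxidative phosphorylation genes, so a change in smooth muscle was not separated from brown-fat RNA or doublets. Ucp1 was at 0.114 (0.068 to 0.18), glycerol kinase (Gk) at 0.133 (0.108 to 0.162) and the mitochondrial coactivator Ppargc1a at 0.147, but Gk was also at 0.149 and Ppargc1a at 0.099 in T- or NK-like nuclei. Glycolysis and hypoxia genes had a median of -0.62, with hexokinase Hk2 at 0.28, and cholesterol-synthesis genes -0.49, with a counting range that included 0 and the mevalonate-pathway enzyme Hmgcs1 at 0.555. The carbonic anhydrase genes (0.10), the bicarbonate and proton transport genes (0.20), resident macrophage genes (0.35), immediate early and heat shock genes (0.20), circadian clock genes (0.35), mitochondrially encoded oxidative phosphorylation genes (-0.26) and sex-linked genes (-0.05) had medians within the range of random lists. Hpse2 (heparanase 2) was at 6.15 (4.81 to 7.91), or 3.14 at a finer clustering that set the pericyte-like nuclei apart, and the interferon-induced GTPase Iigp1 at 5.27 (3.92 to 7.13).

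In macrophage-like nuclei, 988 genes were at least 2-fold higher and 234 lower; giving each nucleus equal weight made the split 605 and 337. The resident macrophage genes had a median of -1.31, with 12 of 13 lower, including the scavenger receptor Cd163 at 0.237 (0.2 to 0.28), the mannose receptor Mrc1 at 0.356 and factor XIII subunit F13a1 at 0.255. Cd163, Mrc1 and F13a1 were also markers that named the class. The mix of clusters differed too. Cluster 13 held 44.8% of macrophage-like nuclei in untreated and 4.63% in high-fat. Cluster 2 held 14.9% and 56.1%, and cluster 5 held 30.2% and 38.2%. Within cluster 2 alone the median was 0.19 and within cluster 5 it was 0.54, while within cluster 13 it kept its direction at -0.22. The foam-cell genes had a median of -0.20, within the range of random lists, with the elastase Mmp12 at 1.64 and the lipid-droplet coat Plin2 at 0.618. Within cluster 2 that median was 0.18 and within cluster 13 it was 0.46, while within cluster 5 it was -0.088. These medians leave out the unnamed cluster led by St18 and Msr1, which held 24.1% of the high-fat and 0.765% of the untreated nuclei. With another clustering seed, a cluster with St18, Ms4a7, Atp6v0d2 and Msr1 among its leading genes was named macrophage-like. It held 12357 high-fat and 357 untreated nuclei. Interferon-response genes had a median of 0.58, with Ifit1 at 3.57. The largest differences included the antibody genes Igkc (20.9, 12.6 to 37.6) and Jchain (16.8, 6.43 to 62.7) and the matrix gene Lum (8.13), which macrophages do not make. Lower were Siglech (0.049), a receptor of plasmacytoid dendritic cells, the histamine enzyme gene Hdc (0.076) and Adgre4 (0.119), an adhesion receptor of myeloid cells. The main clustering named no monocyte or dendritic class. At Leiden resolution 2, a cluster with Adgre4 among its leading genes was named monocyte- or dendritic-like. It held 2.17% of untreated and 0.58% of high-fat nuclei, so a different share of such cells was not separated from a change in macrophages.

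Fibroblast-like nuclei showed 891 genes at least 2-fold higher and 567 lower, with cluster 4 holding 92.1% of them in untreated and 23.1% in high-fat and cluster 10 the rest. The collagenase Mmp13 was at 20.9 (14.6 to 30.9) and Igkc at 30.8 (14.8 to 77.2), and Colq, with 0 untreated counts, was at least 18.6-fold higher. Errfi1, a feedback inhibitor of EGF receptor signalling, was at 0.108, Ppp2r2b, a phosphatase subunit, at 0.088 and Rtl4 at 0.062. Foam-cell genes had a median of 1.24, with 19 of 20 higher, among them Spp1 at 6.35 (6.08 to 6.62), which was also at 6.51 in brown-adipocyte-like nuclei. Immediate early genes had a median of -0.80, with Nr4a1 at 0.163 and Egr1 at 0.344. At Leiden resolution 2, a fibroblast-like cluster of 2799 high-fat and 105 untreated nuclei had Tnfrsf11b, Lum and Timp1 among its leading genes. These genes are on the modulation list. In none of the comparisons were fibroblasts therefore separated from smooth muscle cells that had left the contractile state. In endothelial-like nuclei 221 genes were higher and 348 lower, or 175 and 480 with TMM factors; cluster 8 held 56.0% of them in untreated and 29.7% in high-fat, and cluster 14 held 20.3% and 59.5%. Their immediate early genes had a median of -0.46, with 14 of 15 lower; the shear-responsive factors Klf2 and Klf4 were at 0.422 (0.39 to 0.46) and 0.403. Their modulation genes had a median of 1.02, with Thbs1 at 3.53 and Fn1 at 2.23. Aoah (8.19), the calcium channel Cacna1d (7.23) and the muscarinic receptor Chrm2 (5.47) were higher. At Leiden resolution 2, Aoah was also among the leading genes of an unnamed cluster led by St18 and Ms4a7. That cluster held 16.9% of high-fat and 0.29% of untreated nuclei. For Aoah, free RNA or doublets were therefore not separated from a change in endothelial-like nuclei. Cyp1a1, the oxidase induced through the aryl hydrocarbon receptor, had 0 counts in high-fat and was at least 10.3-fold lower; the brown-fat cytochrome oxidase gene Cox8b had 3 counts (0.055, 0.011 to 0.163) and Hdc was at 0.071. TMM factors shifted the median of all genes by -0.13 in endothelial-like and by -0.10 in fibroblast-like nuclei. The endothelial-like values rest on 760 high-fat nuclei and leave out the unnamed cluster led by Ddah1, Edn1 and Fbln5.

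Treatment of established lesions asks whether inhibiting carbonic anhydrase moves the high-fat aorta back towards the untreated one. The MTZ-after library held fewer macrophage-like and more smooth-muscle-like nuclei than the high-fat library. Foam-cell transcripts were lower in smooth-muscle-like and fibroblast-like nuclei, and in T- or NK-like and B-cell-like ones too, so free RNA or doublets were not separated from a change in these nuclei. Macrophage-like nuclei held more resident-type transcripts, with a different mix of clusters. Both MTZ libraries were compared with the same high-fat library, so part of what they share can come from that library.

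Macrophage-like nuclei made up 12.6% of named nuclei in MTZ-after, a ratio to high-fat of 0.26 (0.249 to 0.272). Without surrounding tissue the ratio was 0.461, with centring 0.545 and with doublet calls kept in 0.164. Smooth-muscle-like nuclei made up 13.1% (2506 nuclei), a ratio of 5.25 (4.77 to 5.79), which was 9.30 without surrounding tissue and 2.52 with centring. Endothelial-like nuclei made up 14.4%, a ratio of 3.83 that turned to 0.857 with stricter filters and 0.834 with centring. Fibroblast-like nuclei made up 10.8% (ratio 0.516, or 0.913 without surrounding tissue and 1.08 with another clustering seed).

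In smooth-muscle-like nuclei, 404 genes were at least 2-fold higher and 27 lower in MTZ-after; the high-fat library held fewer of these nuclei, so the count minimum asks more of genes that are higher in high-fat. With no minimum count the split was 1442 and 1445. Of the 431 calls, 202 were shared with a finer clustering, 283 with another clustering seed and 120 after thinning. Cluster 7 held 90.1% of them in high-fat and 89.8% in MTZ-after. The foam-cell genes had a median of -0.47, with 17 of 20 lower, including the lysosomal proteases Ctsd (0.406) and Ctsb (0.442, 0.39 to 0.5). Spp1 was at 0.35 (0.326 to 0.376), lysozyme (Lyz2) at 0.355 and Ctsl at 0.401. Spp1 was also at 0.344 in B-cell-like nuclei, where the foam-cell list had a median of -0.52, and in T- or NK-like nuclei that list was at -0.86. Contractile genes (-0.05) and modulation genes (-0.09) had medians within the range of random lists, with calponin (Cnn1) at 0.476 and the myosin light-chain kinase Mylk at 1.28. The TGF-beta response genes had a median of -0.21, with elastin (Eln) at 0.684. Carbonic anhydrase genes had a median of -0.43, with 6 of 7 lower and Car3 at 0.502, but the counting range of this median included 0. The median was 0.016 with the highest doublet scores removed by the same rule in every library. The bicarbonate and proton transport genes had a median of -0.30, which was 0.029 with each nucleus given equal weight. Fosb, a subunit of the AP-1 factor, was at 6.90 (3.81 to 13.9), and Fos at 1.82. Titin (Ttn), with 0 counts in high-fat, was at least 4.79-fold higher, and the platelet chemokine gene Ppbp, with 2 counts, was at 10.4 (2.80 to 87.1).

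Macrophage-like nuclei showed 279 genes at least 2-fold higher and 189 lower, or 234 and 246 with TMM factors. Resident macrophage genes had a median of 0.89, with 10 of 13 higher, among them Timd4 (3.47), a phosphatidylserine receptor, F13a1 (2.64), Cd163 (2.35) and Pf4 (4.10). Cluster 13 held 31.1% of these nuclei against 4.63% in high-fat, and cluster 2 held 35.0% against 56.1%. Within cluster 5 alone the median was -0.19 and within cluster 13 it was -0.15, while within cluster 2 it was 0.20. Foam-cell genes had a median of -0.25, with Mmp12 at 0.689 and the fatty-acid carrier Fabp5 at 0.605. The median turned to 0.058 with doublet calls kept in, to 0.072 with another clustering seed and to 0.084 within cluster 5, but was -0.10 within cluster 2 and -0.44 within cluster 13. The vomeronasal receptor Vmn2r26 (15.4, 10.3 to 23.8), Adgre4 (8.99) and Serpinb2 (8.46), the plasminogen activator inhibitor of macrophages, were higher. Vmn2r26 and Serpinb2 were among the leading genes of cluster 23, which held 7.51% of these nuclei against 0.39% in high-fat. Adgre4 was among those of cluster 13, and of the monocyte- or dendritic-like cluster at Leiden resolution 2. The latter held 1.99% of all kept nuclei in MTZ-after against 0.58% in high-fat. Igkc (0.136), Jchain (2 counts, 0.075, 0.009 to 0.275) and the secreted Wnt inhibitor Frzb (0.23) were lower.

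Fibroblast-like nuclei showed 329 genes at least 2-fold higher and 326 lower, with cluster 4 holding 84.4% of them against 23.1% in high-fat. Mmp13 was at 0.045 (0.024 to 0.078), the mechanical-stress gene Ankrd1, with 2 counts, at 0.047 (0.006 to 0.175) and Igkc at 0.146. Ppbp (12.1), the Wnt agonist Rspo3 (8.86) and the IGF-binding gene Igfbp6 (8.77) were higher. Foam-cell genes had a median of -0.85, with 17 of 20 lower, including Lgals3 (0.32) and Gpnmb (0.377), modulation genes -0.73 and interferon-response genes 0.66. In endothelial-like nuclei 616 genes were higher and 117 lower; cluster 19 held 38.2% of them against 7.24% in high-fat. ER-stress genes had a median of -0.43, with 10 of 10 lower, and EndMT genes -0.24, with Edn1 at 0.41 (0.37 to 0.45) and Fn1 at 0.496. Lipogenesis genes had a median of 0.97, with the desaturase Scd1 at 3.89, and brown-fat genes 1.38, where brown-adipocyte-like nuclei made up 16.1% against 3.35%. The RNA-editing homologue Adarb2 was at 8.57 (6.68 to 11.2), Chst8, with 2 counts, at 23.7 (6.34 to 199.8) and alkaline phosphatase (Alpl), with 1 count, at 33.8 (5.81 to 1362). The guidance cue Slit2 (0.224), Ctnnd2 (0.187) and Frzb (0.248) were lower. For these endothelial-like values the high-fat reference was 760 nuclei with a median of 2071 UMIs, against 775 in MTZ-after. That reference left out the unnamed cluster led by Ddah1, Edn1 and Fbln5.

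Giving MTZ together with the diet asks whether inhibition during lesion growth keeps the aorta closer to the untreated one. The MTZ-simultaneous library held smooth-muscle-like nuclei with more contractile and fewer modulation, matrix and foam-cell transcripts than the high-fat library. The 4 lists differed in the same direction in macrophage-like, T- or NK-like and B-cell-like nuclei, so free RNA or doublets were not separated from a change in smooth muscle. Macrophage-like nuclei were a smaller share and held fewer foam-cell transcripts. Circadian output genes were higher across classes.

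Macrophage-like nuclei made up 22.3% of named nuclei, a ratio to high-fat of 0.458 (0.441 to 0.476). The ratio was 0.768 without surrounding tissue, 0.662 with centring and 0.29 with stricter filters. Those filters gave a smooth-muscle-like cluster of 1769 nuclei of which 49.0% were macrophage-like in the main clustering. Smooth-muscle-like nuclei made up 15.2% (2333 nuclei), a ratio of 6.10 (5.54 to 6.73), which was 10.2 without surrounding tissue and 2.17 with centring. Endothelial-like nuclei made up 14.2%, a ratio of 3.79 that turned to 0.663 with stricter filters, 0.723 with centring and 0.746 with doublet calls kept in. Fibroblast-like nuclei made up 11.0% (ratio 0.524, or 0.879 without surrounding tissue and 1.07 with another clustering seed).

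In smooth-muscle-like nuclei, 632 genes were at least 2-fold higher and 22 lower; simulated libraries of these depths called 235 unchanged genes among 10614. The split turned to 1205 higher and 1732 lower with no minimum count, and thinning gave 216 and 14. Of the 654 calls, 257 were shared with a finer clustering, 325 with another clustering seed and 83 after thinning. Cluster 20 held 49.0% of the nuclei against 9.90% in high-fat, and cluster 7 held 51.0% against 90.1%. With another clustering seed, a smooth-muscle-like cluster held 762 MTZ-simultaneous and 12 high-fat nuclei, with a median of 1.8 times the library median of UMIs. Its leading genes included Agbl1 and Cacna1e, which also led the B-cell-like cluster, so mixed nuclei were not excluded. Contractile genes had a median of 0.14, with 13 of 18 higher, including Actg2 (2.86, 2.13 to 3.92), smoothelin (Smtn, 1.49), Myh11 (1.47, 1.35 to 1.58) and tropomyosin (Tpm1, 1.40). Outside smooth muscle Myh11 was higher too, at 289.7 CPM against 120.9 CPM in T- or NK-like nuclei. With every nucleus thinned to 500 UMIs, the share with a Myh11 UMI was 16.4% against 6.46% in T- or NK-like, 15.2% against 5.49% in macrophage-like and 43.5% against 38.8% in smooth-muscle-like nuclei. Modulation genes had a median of -0.44, with 16 of 19 lower, including the stromelysin Mmp3 at 0.226. Foam-cell genes had a median of -0.39, with Ctsd at 0.418 and Ctsb at 0.437. Collagen and elastic-fibre genes had a median of -0.25, with Eln at 0.51 (0.48 to 0.54), and calcification genes -0.40, with a counting range that included 0 and the bone factor Runx2 at 0.668. In macrophage-like nuclei the medians were 0.68 for contractile, -0.23 for modulation, -0.48 for foam-cell and -0.35 for collagen genes. In T- or NK-like nuclei they were 0.64, -0.27, -0.64 and -0.27, and in B-cell-like nuclei 0.38, -0.21, -0.77 and -0.35. Interferon-response genes had a median of -0.40, with 15 of 18 lower, including Gbp3 (0.479). Immediate early and heat shock genes had a median of -0.43, with Hspa1b at 0.218, but 0.061 at a finer clustering. Lipogenesis genes had a median of 0.41, with the triglyceride-forming enzymes Dgat1 (2.77) and Dgat2 (2.60), and brown-fat genes 1.27, with Ppargc1a at 3.31, in a library with 8.60% brown-adipocyte-like nuclei against 3.35%. Spp1 was at 0.253 (0.237 to 0.271), against 0.272 in B-cell-like nuclei, the lipase Pnpla3 at 0.282 and Hpse2 at 0.311, which was 1.20 at a finer clustering that set pericyte-like nuclei apart. Slpi, an antiprotease, was at 11.5 (2 counts, 3.15 to 95.7) and the kinesin Kifc3 at 15.0 (1 count, 2.64 to 595.9), and Tmem132b, with 0 counts in high-fat, was at least 3.58-fold higher.

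Macrophage-like nuclei showed 372 genes at least 2-fold higher and 147 lower, or 300 and 208 with TMM factors, which shifted the median of all genes by -0.10. Foam-cell genes had a median of -0.48, with 17 of 20 lower, including Mmp12 (0.458), Ctsb (0.524) and Ctsd (0.528); within cluster 5 alone it was 0.026, within cluster 2 -0.55 and within cluster 13 -0.40. Resident macrophage genes had a median of 0.52, with 12 of 13 higher, including Timd4 (5.21), Pf4 (3.47) and F13a1 (1.63). Within cluster 5 it was -0.043, within cluster 13 -0.089 and within cluster 2 0.44. Cluster 23, led by Vmn2r26, Alox15 and Padi4, held 19.7% of these nuclei against 0.39% in high-fat. Retnla, a gene of alternatively activated macrophages, was at 24.5 (19.1 to 32.0) and Vmn2r26 at 35.3, and Syt4, with 0 counts in high-fat, was at least 38.2-fold higher. The MTZ-simultaneous library also held more mesothelial-like nuclei (15.3% against 0.276% of named nuclei). A difference in the tissue sampled was therefore not separated from a change in macrophages. Spp1 (0.302), Mfge8 (0.288), which bridges dying cells to phagocytes, and Cd5l (0.309), an inhibitor of macrophage apoptosis, were lower.

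Fibroblast-like nuclei showed 373 genes at least 2-fold higher and 367 lower, with cluster 4 holding 77.3% of them against 23.1% in high-fat. The hedgehog-binding Hhip (15.8, 9.89 to 26.6), Igfbp6 (10.2) and the glypican Gpc3 (8.37) were higher. Mmp13 (0.074, 0.051 to 0.105), the BMP antagonist Grem1 (0.134) and Spp1 (0.211) were lower. Foam-cell genes had a median of -0.91, with 19 of 20 lower, and modulation genes -0.54. In endothelial-like nuclei 322 genes were higher and 112 lower, or 422 and 74 with each nucleus given equal weight; cluster 14 held 38.8% of them against 59.5%. Immediate early genes had a median of -0.80, with Fos at 0.374, ER-stress genes -0.46, with 10 of 10 lower, and EndMT genes -0.29, with Edn1 at 0.478. Pcdh17 (0.181) and Nos1 (0.216) were lower, and Syt4, with 0 counts in high-fat, was at least 6.06-fold higher. The same 760 high-fat nuclei were the endothelial-like reference, without the unnamed cluster led by Ddah1, Edn1 and Fbln5. Clock genes had a median of 1.16 in endothelial-like, 1.02 in fibroblast-like, 0.86 in macrophage-like and 0.56 in smooth-muscle-like nuclei. The output factors Dbp and Hlf were at 7.49 and 5.05 in endothelial-like nuclei, and the core activator Arntl was at 0.254. In high-fat over untreated, Dbp was higher and Arntl lower beyond counting error in 5 of the 8 compared classes.

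**Figure D3:**
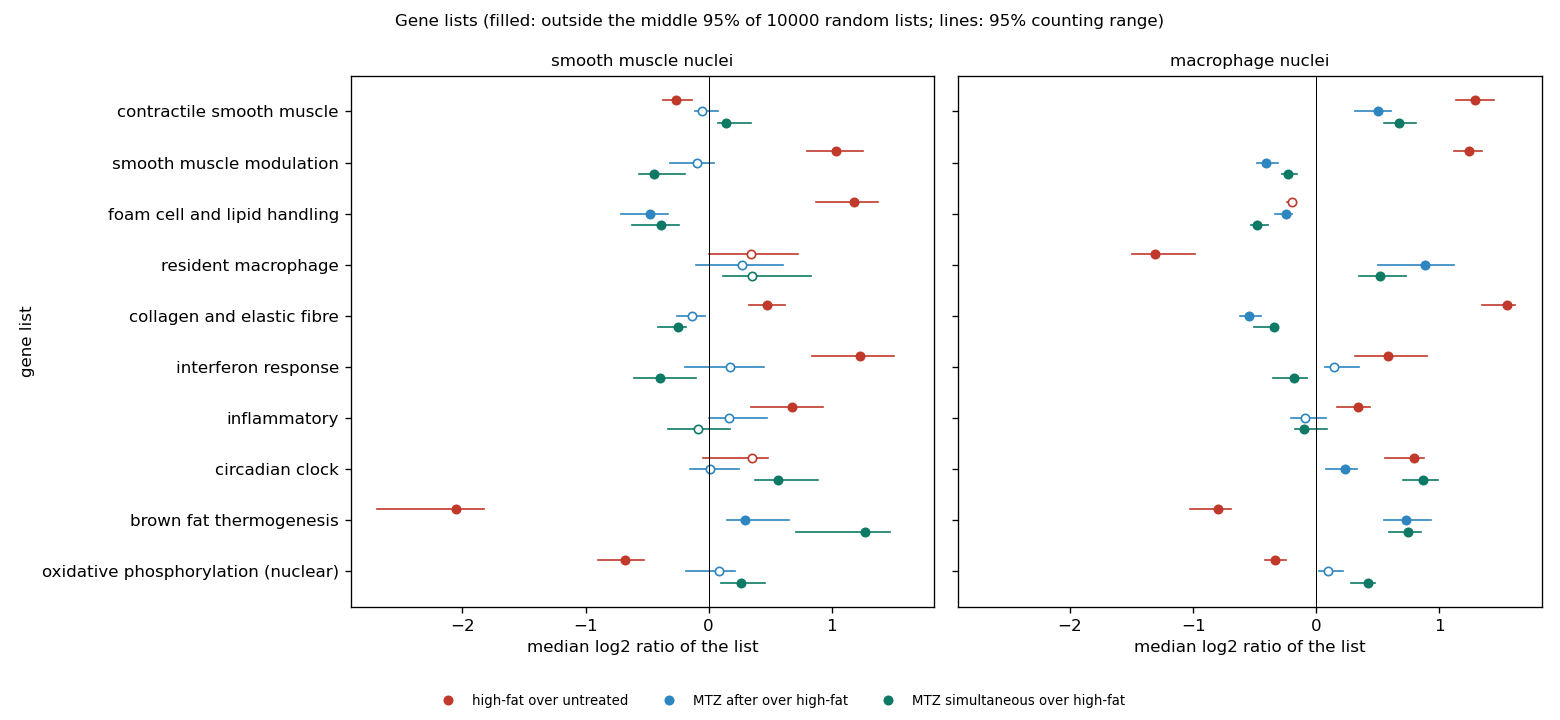
Median log2 ratio of 10 gene lists (points, filled outside the central 95% of 10000 random lists, with 95% counting ranges) in smooth-muscle-like and macrophage-like nuclei for the 3 comparisons. The modulation list sat at 1.03 in smooth-muscle-like nuclei for high-fat over untreated and at -0.44 for MTZ-simultaneous over high-fat.

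The timing of MTZ was compared directly between the MTZ libraries. Smooth-muscle-like nuclei held more contractile transcripts in MTZ-simultaneous, and all 4 large classes held fewer interferon-response transcripts. The gene counts, list medians and gene ratios of this comparison were not recomputed under the alternative settings. In smooth-muscle-like nuclei 227 genes were at least 2-fold higher and 280 lower in MTZ-simultaneous than in MTZ-after. Their contractile genes had a median of 0.31, with 14 of 18 higher, interferon-response genes -0.35 and immediate early genes -0.35. The contractile list was also at 0.38 in macrophage-like and 0.28 in T- or NK-like nuclei, the latter within the range of random lists. In thinned T- or NK-like nuclei the share with a Myh11 UMI was 16.4% against 11.5%, and in smooth-muscle-like nuclei 43.5% against 41.8%. The clusters also differed: cluster 20 held 49.0% of smooth-muscle-like nuclei against 10.2%, and cluster 19 held 8.77% of endothelial-like nuclei against 38.2%. Of macrophage-like nuclei, cluster 23 held 19.7% against 7.51% and cluster 13 held 17.8% against 31.1%. The interferon-response median was -0.50 in macrophage-like, -0.64 in fibroblast-like and -0.69 in endothelial-like nuclei. The split was 266 and 199 genes in macrophage-like, 145 and 234 in fibroblast-like and 165 and 541 in endothelial-like nuclei. Retnla was at 6.26 (4.72 to 8.46) in macrophage-like nuclei, and Ppbp was at 0.075 in smooth-muscle-like, 0.123 in macrophage-like, 0.064 in fibroblast-like and 0.062 in endothelial-like nuclei. Car1 over all nuclei was at 2.37.

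Whether the MTZ libraries lay closer to the untreated one was measured on genes picked with one part of the high-fat nuclei and compared with the other part. In smooth-muscle-like nuclei, 57 genes higher in high-fat had a median log2 ratio of -0.32 (-0.44 to -0.26) in MTZ-after, 77.2% of them towards untreated, and -0.61 (-0.68 to -0.52) in MTZ-simultaneous, 94.7% of them. The 478 lower genes had medians of 0.12 and 0.28. In macrophage-like nuclei the 690 higher genes had medians of -0.17 in both libraries, and the 245 lower genes 0.82 and 0.71. In fibroblast-like nuclei the medians were -0.60 and -0.76 for the higher genes and 0.96 and 1.09 for the lower genes. In endothelial-like nuclei they were -0.27 and -0.75 for the higher genes but 0.88 and 0.49 for the lower genes, so the order of the MTZ libraries differed between these sets. For MTZ-after and MTZ-simultaneous, random genes had medians of -0.026 and -0.065 (higher) and -0.043 and -0.007 (lower) in smooth-muscle-like nuclei. In macrophage-like nuclei these were -0.004 and 0.07, and 0.034 and 0.10. In fibroblast-like nuclei they were -0.024 and 0.013, and -0.002 and 0.022, and in endothelial-like nuclei -0.016 and -0.014, and 0.09 and 0.064. Splitting the nuclei removes shared counting error but not what is particular to the single high-fat library, which picked the genes and was the reference for both MTZ libraries. These medians therefore do not separate an effect of MTZ from a high-fat library that was itself out of line.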

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

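Of the tests below, those on nuclei with at least 2000 UMIs and on the number of libraries were set out before their results were seen, and the others were chosen only after the result was seen.

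Car1 stood out because the MTZ libraries lay on opposite sides of the high-fat library, at 0.743 in MTZ-after and 1.76 in MTZ-simultaneous; that difference was not tested. A candidate explanation for counts in every class is free RNA: over all nuclei thinned to 500 UMIs, the share with Car1 (6.67, 4.28, 3.11 and 7.22% from untreated to MTZ-simultaneous) had the library order of the red-cell gene Hbb-bs (19.5, 17.2, 9.56 and 27.9%). As the whole of the endothelial-like counts, free RNA released with globin transcripts is argued against, since the ratio of Car1 to Hbb-bs was at least 2.14 times that in macrophage-like nuclei in each library. Part of that ratio came from Hbb-bs, whose thinned share in high-fat was 21.5% in macrophage-like against 9.87% in endothelial-like nuclei. At 500 UMIs the intervals of their Car1 shares overlapped in MTZ-after (2.63 to 4.09% against 3.20 to 4.68%) and MTZ-simultaneous (6.74 to 8.55% against 8.39 to 10.9%). In untreated and high-fat the intervals did not overlap, so the higher endothelial-like Car1 share at equal depth was beyond counting error there. In the MTZ libraries the endothelial-like share was also the higher, at 3.89% against 3.30% in MTZ-after and 9.59% against 7.61% in MTZ-simultaneous. Overlap of intervals does not decide whether these differences were beyond counting error, and no interval of the difference was computed. Other free RNA is argued against in endothelial-like nuclei too. By CPM, Car1 stood there at least 1.42 times above all other nuclei in each library. Hbb-bs, Hba-a1, Myh11 and Lyz2 were at most 0.984. Lum was at most 0.614 except in untreated, at 1.46 (1.29 to 1.64) against 2.19 (2.09 to 2.30) for Car1. In the other classes free RNA, from red cells or elsewhere, and low expression cannot be told apart, as 1 of 6 classes (adipocyte-like, at least 1.47) had a ratio of Car1 to Hbb-bs above that of macrophage-like nuclei in every library and the highest class stood at most 1.76 times above the lowest; an effect of MTZ stays untested.

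The larger macrophage-like share in high-fat is the pattern the diet would give. A smaller share of the surrounding-tissue classes in the high-fat sample is argued against as the whole of it, because the ratio to untreated was 2.12 without those classes. Mesothelial-like nuclei stayed in that base, at 8.68% of it in untreated and 0.178% in high-fat. Unnamed nuclei stayed as well, at 27.0% and 47.6%, so the test cannot exclude less of other surrounding tissue. Shallow droplets holding macrophage RNA are argued against too, as the whole of the pattern. Among nuclei with at least 2000 UMIs the share was 23.2% in high-fat and 9.14% in untreated, a ratio of 2.54 (2.33 to 2.78). That cut lay near the median of kept nuclei in untreated (2030 UMIs) and far above it in high-fat (954 UMIs). It kept unlike parts of these libraries, and remaining doublets among the deeper nuclei were not excluded. With 1 library per group, the diet and any other difference between these samples cannot be told apart.

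Clock genes set the MTZ-simultaneous library apart from the high-fat library, and the high-fat library from the untreated one. Beyond counting error, Dbp was higher and Arntl lower in 8 of 8 compared classes for the former and in 5 of 8 for the latter, which is what different times of day at collection may give; collection times were not given in the sources used here. For MTZ-simultaneous over high-fat, free RNA of a single class cannot be told apart from a shared difference by the spread of the Dbp difference over classes, in which the largest was 2.96 times the smallest but the intervals overlapped. An effect of MTZ on the clock also stays open and was not tested.

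Several groups of nuclei that no comparison used were larger in a treated library than in the untreated one, and these differences were not tested. Adrenal-cortex-like nuclei made up 15.8% of kept nuclei in MTZ-after and 0.005% in untreated. Mesothelial-like nuclei made up 14.4% in MTZ-simultaneous and 6.12% in untreated. The unnamed cluster led by St18 and Msr1 made up 24.1% in high-fat and 3.63% in MTZ-after, against 0.765% in untreated. The unnamed cluster led by Ddah1 and Edn1 made up 17.7% in high-fat and 6.52% in MTZ-after, against 1.09% in untreated. A cluster with the chromogranin genes Chga and Chgb made up 5.85% of MTZ-after, and a cluster with the liver genes Cyp3a25 and Cps1 made up 3.35%; untreated held 0 of 20780 nuclei of either, which allows a share of up to 0.018%.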

How the results depend on the processing

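Alternatives on doublets, the clustering seed and the base of all kept nuclei were added after seeing the data. The one on doublets removed the highest 8% of scores in every library, with ties kept. Also added then were each macrophage-like cluster alone and the leaving out of some smooth-muscle-like clusters. The same holds for all alternatives on shares and list medians of endothelial-like and fibroblast-like nuclei. The others were planned. Moved means outside the reported counting interval, or for counts of genes by more than 1.5 times. Of 2838 alternative list medians in the 4 large classes 2174 stayed inside, 637 moved and 27 turned direction; of 723 for named genes the numbers were 565, 157 and 1. A list counts as turned here and below only where its reported median lay outside the range of random lists, and a ratio only where its interval left out 1. Among the other lists 268 values changed sign and are not listed here, and among the other named genes 13. For Car1 26 of 33 values stayed inside and 0 turned, but clustering and count minimums cannot move a sum over all nuclei. All 27 macrophage-like share values moved and 0 turned; of 33 smooth-muscle-like share values 28 moved and 4 turned, and 9 endothelial-like and 4 fibroblast-like ones of 27 each turned. Of 66 counts of genes in smooth-muscle-like nuclei 34 moved (the other large classes were recounted with TMM factors and equal weight alone), and of 32 return medians 19 moved and 0 turned. The high-fat library held 505 smooth-muscle-like nuclei, and counts this low limit which genes can be called. Looser filters and centring were run for shares alone. The comparison of the MTZ libraries with each other was not run under any alternative. The cause was not tested for any change below, except that count minimums, pseudocounts and thinning change the number of genes that can pass.

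Values follow in the order high-fat over untreated, MTZ-after over high-fat and MTZ-simultaneous over high-fat, and where fewer moved, by the library in the numerator. As reported, the smooth-muscle-like share ratios were 0.616, 5.25 and 6.10, the macrophage-like ones 3.78, 0.26 and 0.458, the endothelial-like ones 0.199, 3.83 and 3.79, the fibroblast-like ones 1.75, 0.516 and 0.524, the Car1 ratios 0.674, 0.743 and 1.76, the genes higher in smooth-muscle-like nuclei 151, 404 and 632 and those lower 346, 27 and 22. With at least 500 genes and at most 5% mitochondrial counts, the smooth-muscle-like share ratio was 1.34, 3.40 and 4.71, the macrophage-like share ratio 4.02, 0.243 and 0.290 and the endothelial-like share ratio turned to 1.46, 0.857 and 0.663. Here the genes lower numbered 136, 60 and 53. In macrophage-like nuclei of MTZ-simultaneous the lipogenesis list turned from 0.34 to -0.10 and the brown fat list from 0.74 to -0.043. Leaving out here a cluster of which 49.0% was macrophage-like as reported, the smooth-muscle-like share ratio was 1.42, 3.10 and 2.70. With at least 200 genes and at most 20% mitochondrial counts, the smooth-muscle-like share ratio was 0.962, 3.88 and 4.99, the macrophage-like share ratio 4.26, 0.217 and 0.346 and the endothelial-like share ratio turned to 1.07 in high-fat. With doublet calls kept in, the smooth-muscle-like share ratio was 0.933, 3.51 and 5.32, the macrophage-like share ratio 4.61, 0.164 and 0.290 and the endothelial-like share ratio turned to 1.33 in high-fat and 0.746 in MTZ-simultaneous. Here the genes lower numbered 36 in MTZ-simultaneous. In macrophage-like nuclei of MTZ-after the foam cell list turned from -0.25 to 0.058 and in macrophage-like nuclei of MTZ-simultaneous the inflammatory list turned from -0.097 to 0.004 and the lipogenesis list from 0.34 to -0.049. At Leiden resolution 2, the smooth-muscle-like share ratio was 0.833, 3.45 and 5.15 and the macrophage-like share ratio 4.25, 0.208 and 0.329. Here the genes lower numbered 165, 67 and 34. In smooth-muscle-like nuclei of MTZ-simultaneous the immediate early list turned from -0.43 to 0.061 and in macrophage-like nuclei of high-fat the immediate early list turned from -0.20 to 0.034. Hpse2 in smooth-muscle-like nuclei of MTZ-simultaneous was 1.20 in place of 0.311. Without its cluster of which 59.9% was fibroblast-like as reported, the smooth-muscle-like share ratio was 0.835, 3.79 and 5.36. With each library centred before the principal components, the smooth-muscle-like share ratio was 1.23, 2.52 and 2.17, the macrophage-like share ratio 1.78, 0.545 and 0.662 and the endothelial-like share ratio turned to 1.23, 0.834 and 0.723. With the highest 8% of doublet scores removed in every library, the smooth-muscle-like share ratio was 1.18, 3.81 and 4.24 and the macrophage-like share ratio 4.72, 0.202 and 0.298. Here the genes higher numbered 84 in high-fat and those lower 128 in high-fat. In smooth-muscle-like nuclei of MTZ-after the carbonic anhydrase list turned from -0.43 to 0.016 and in endothelial-like nuclei of MTZ-after the bicarbonate transport list turned from -0.22 to 0.19 and the foam cell list from -0.33 to 0.023. Under another clustering seed, the smooth-muscle-like share ratio was 0.920 in high-fat and 5.83 in MTZ-after, the macrophage-like share ratio 5.23, 0.278 and 0.293 and the fibroblast-like share ratio turned to 0.931, 1.08 and 1.07. Here the genes lower numbered 165, 52 and 47. In macrophage-like nuclei of MTZ-after the foam cell list turned from -0.25 to 0.072. Without the surrounding-tissue classes, the smooth-muscle-like share ratio was 0.346, 9.30 and 10.2, the macrophage-like share ratio 2.12, 0.461 and 0.768 and the fibroblast-like share ratio turned to 0.982 in high-fat. Over all kept nuclei, the smooth-muscle-like share ratio was 0.438, 7.08 and 9.98 and the macrophage-like share ratio 2.68, 0.351 and 0.750.

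Using TMM factors, the Car1 ratio was 0.613, 0.675 and 1.60. Here the genes higher numbered 88 in high-fat. Giving each nucleus equal weight, the Car1 ratio was 0.613 in high-fat and 1.85 in MTZ-simultaneous. In smooth-muscle-like nuclei of MTZ-after the bicarbonate transport list turned from -0.30 to 0.029. After thinning to equal depth, the Car1 ratio was 0.626 in high-fat. Here the genes higher numbered 37, 239 and 216 and those lower 84, 11 and 14. In smooth-muscle-like nuclei of high-fat the TGF-beta response list turned from 0.35 to -0.095. With a minimum of 20 counts, the genes higher numbered 439, 998 and 1125 and those lower 672, 86 and 86. With no minimum count, the genes higher numbered 2646, 1442 and 1205 and those lower 1094, 1445 and 1732. With a pseudocount of 10 CPM, the Car1 ratio was 1.68 in MTZ-simultaneous. Here the genes higher numbered 174 in MTZ-after and 123 in MTZ-simultaneous and those lower 204 in high-fat. Within macrophage-like cluster 2, the resident macrophage list turned from -1.31 to 0.19, the inflammatory list from 0.34 to -0.003, the TGF-beta response list from 0.55 to -0.054 and the circadian clock list from 0.79 to -0.013 in high-fat. Within cluster 5, the resident macrophage list turned from -1.31 to 0.54 in high-fat and the foam cell list turned from -0.25 to 0.084 and the resident macrophage list from 0.89 to -0.19 in MTZ-after and the foam cell list turned from -0.48 to 0.026, the resident macrophage list from 0.52 to -0.043 and the lipogenesis list from 0.34 to -0.19 in MTZ-simultaneous. Within cluster 13, the calcification list turned from 0.71 to -0.003 and the ER stress list from 0.30 to -0.058 in high-fat and the resident macrophage list turned from 0.89 to -0.15 in MTZ-after and the resident macrophage list turned from 0.52 to -0.089 in MTZ-simultaneous. Exchanging the parts gave smooth-muscle-like medians of -0.23 for the higher genes of MTZ-after and -0.45 for the higher genes of MTZ-simultaneous, macrophage-like medians of -0.12 for the higher genes of MTZ-after, 0.92 for the lower genes of MTZ-after and -0.11 for the higher genes of MTZ-simultaneous and endothelial-like medians of -0.37 for the higher genes of MTZ-after and -0.91 for the higher genes of MTZ-simultaneous. Leaving out the split gave smooth-muscle-like medians of 0.44 for the lower genes of MTZ-after, -0.50 for the higher genes of MTZ-simultaneous and 0.64 for the lower genes of MTZ-simultaneous, macrophage-like medians of -0.14 for the higher genes of MTZ-after, 0.94 for the lower genes of MTZ-after and -0.15 for the higher genes of MTZ-simultaneous, fibroblast-like medians of -0.57 for the higher genes of MTZ-after and 0.98 for the lower genes of MTZ-after and endothelial-like medians of -0.42 for the higher genes of MTZ-after, 1.28 for the lower genes of MTZ-after, -0.85 for the higher genes of MTZ-simultaneous and 0.89 for the lower genes of MTZ-simultaneous.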

Other observations

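The other classes with enough nuclei in every library gave further values. In T- or NK-like nuclei of high-fat, Spp1 (5.60), Cd5l (6.94) and Col1a1 (6.16) were higher than in untreated, and the brown-fat genes Cidea (0.087) and Ppargc1a (0.099) lower. Cd5l, Col1a1 and Cidea are genes of macrophages, fibroblasts and brown adipocytes. B-cell-like nuclei showed the same kind of genes, with Col1a1 at 10.5 (6.99 to 16.4) and Ucp1 at 0.067. In MTZ-simultaneous over high-fat, T- or NK-like nuclei held more Lef1 (2.91, 2.13 to 4.05), a transcription factor of naive T cells.

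Adipocyte-like nuclei made up 15.4% of named nuclei in high-fat, against 4.05% in untreated, 4.28% in MTZ-after and 4.97% in MTZ-simultaneous. In high-fat over untreated they showed 1389 genes at least 2-fold higher and 329 lower. Mmp12 was at 11.1 and Cd5l at 11.9, both macrophage genes, while Noct, a clock-controlled gene, was at 0.182 and Pon1 at 0.122. Nnat (neuronatin) was at 4.01 (3.55 to 4.53) in MTZ-after and at 3.26 (2.93 to 3.63) in MTZ-simultaneous over high-fat. Dio2, the deiodinase that activates thyroid hormone, was at 5.04 in MTZ-simultaneous.

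Brown-adipocyte-like nuclei of high-fat held less Ppargc1a than those of untreated (0.223, 0.195 to 0.254), and 245 genes were higher and 646 lower. In MTZ-simultaneous over high-fat the transporter genes Slc5a12 and Slc34a1, which are genes of the kidney tubule, were at least 12.8-fold and at least 12.7-fold higher, with 0 counts in high-fat.

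The share of nuclei like those of lymphatic endothelium was 2.65% in untreated, 0.582% in high-fat, 1.40% in MTZ-after and 2.07% in MTZ-simultaneous. B-cell-like nuclei made up 1.84%, 2.69%, 1.26% and 4.09%, and T- or NK-like nuclei 3.54%, 1.91%, 2.14% and 2.11%. Neuron-like nuclei numbered 115 in MTZ-after and 28 in MTZ-simultaneous, with 0 in the other libraries.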
